A study of Homo sapiens with 6 samples.

How the data were processed

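Total RNA of 6 samples of the human myeloma cell line MM.1S was hybridised to 1-colour Affymetrix-type arrays, with biotin-labelled material made with a whole-transcript kit, per the labels. All samples had a Cfz pulse of 1 h, and 3 were then cultured for 12 h with DMSO and 3 with 10 µM ATRA. Groups and replicate numbers were taken from the labels. The submitters' processing notes name RMA and limma, with no versions and no role for either tool, and the genome build was not given in the sources used here.

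The deposited values of the authors are intensities on a linear scale, 1 per probe set and array, for 53617 probe sets. The range of the values, up to 14038, shows that they are linear, and no value was at or below 0. Their background correction, summarisation and normalization were taken as the authors left them, so any compression of low values by those steps remains in the fold changes. All values were turned to log2 before any test, with no pseudocount. The design chosen before the data were examined had assumed log2 values and foresaw this step. No pair of arrays had identical values.

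Probe sets were named from the platform annotation. Of the 53617 probe sets, 16098 (30.0%) had exactly 1 symbol, 0 had several, and 37519 are unnamed here, so many genes of interest were not analysed here. All 16098 were matched by Entrez ID to a table of human genes on the assembly GRCh38.p14, which served only for names, gene types and neighbourhood, and 0 symbols changed. The 14884 symbols were tested with 1 probe set each, the one with the highest mean over the 6 arrays. There were 779 symbols with several probe sets. Among named genes 7 have several. The probe sets of NRIP1 (0.81 and -0.04) and SEM1 (-0.13 and 0.10) disagreed in sign, those of BMF (1.15 and 0.29), CADM1 (-1.52 and -0.75) and IER3 (1.33 down to 0.38) in size, and those of SCD and CCND2 were close. Values identical to those of another probe set were found for 2113 probe sets, among them those of IER3, and for 6 called genes.

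Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, 2 groups of 3 arrays, no block, no filter on dim genes, two-sided), with Benjamini-Hochberg adjustment over all 14884 genes and a threshold of 0.05. A size filter of 2-fold was applied on top of the test for a second count. SDs are over the 3 arrays of a group, on the scale of the value beside them. Folds are ratios of geometric means.

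Gene lists were written from general knowledge before the data were examined, 24 lists for pathways and cell states and 7 for markers of other cell types. Each was described by its measured members and tested with camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 5 measured members. That minimum was set after the files were seen. Calls that hold with an estimated correlation are those of the replication, mitosis and fatty acid synthesis lists. Set tests speak only for measured members, and 32 genes stand in several lists. The lists of retinoid metabolism, interferon, proteasome and efflux genes lack most or many members among the named probe sets.

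Genes were named by a rule set before the data were examined. It took the 10 largest increases and the 10 largest decreases among called genes with no overlap between groups, leaving out non-coding and uncharacterised symbols, and 1 of the decreases is not reported here. For each list it took up to 4 called members with the largest change or, with none called, the 2 members with the largest difference. A fixed set of genes was added, of which DHRS3, IRF1, IRF4, MYC and MAF were measured. Genes outside the rule are said to be chosen after their values were seen.

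Alternatives chosen before the data were examined were the replicate number as a block, leaving out each array, leaving out the dimmer 50% or 25% of genes, a common median, quantile and cyclic loess normalization, eBayes with trend and robust, array weights, the mean of a gene's probe sets, every probe set by itself, limma's treat at 1.2-fold and an ordinary two-sample test. For lists they were an estimated correlation, ranks, fry and leaving out genes of several lists. Protein-coding genes alone and genes without identical probe sets were added after seeing the data.

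The steps were tested on simulated data for the comparison of ATRA with DMSO, with 14884 genes drawn at each gene's mean and estimated residual SD. Of changed genes, 27.3% were recovered at a log2 change of 0.5 (66 genes), 67.2% at 1 (67 genes) and 98.5% at 2 (67 genes), with 0 wrong signs. Of 138 calls 9 were false (6.52%). The residual SDs are themselves estimates from 6 arrays, and fewer genes were changed than the 565 called in the data. Recovery and the share of false calls therefore hold for these settings and may differ in the real comparison. A list shifted by -0.5 was called and 0 of the other simulated lists were. The noise was drawn independently for each gene, so members of a simulated list were uncorrelated. In the real data the estimated correlation was 0.089 for the replication list and 0.071 for the MYC list. The simulation therefore says nothing about false list calls among correlated genes. Figures were drawn with matplotlib 3.10.9.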

Results

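Gene expression was measured on 6 arrays of MM.1S, a human multiple myeloma cell line. Multiple myeloma is a cancer of plasma cells, the antibody-secreting cells of the B cell lineage. All cells had been pulsed for 1 h with Cfz, the usual abbreviation of carfilzomib, an inhibitor of the proteasome. They were then cultured for 12 h with the solvent DMSO, on 3 arrays, or with 10 µM ATRA (all-trans retinoic acid, the ligand of the retinoic acid receptors), on 3 arrays. The comparison asks how ATRA changed gene expression in cells already exposed to Cfz, and cells without Cfz were not analysed here. Median intensity over all probe sets lay between 9.40 and 9.76 per array and the highest value between 13587 and 14038. Log2 values of the 14884 genes correlated at 0.990 to 0.992 between arrays of 1 group and at 0.985 to 0.987 between arrays of different groups (correlations across genes, which are not independent replicates). The first principal component held 41.3% of the variance, with DMSO arrays between -18.5 and -15.7 and ATRA arrays between 16.9 and 17.8. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, and that spread can be purely technical. The number of arrays limits the precision of each value.

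After ATRA, CALCRL, the receptor that binds calcitonin gene-related peptide and adrenomedullin with its partner proteins, was 35.1-fold higher, at an intensity of 289 ± 9.99 against 8.25 ± 0.683 with DMSO (SD, n = 3 arrays each). The DMSO value lay under the median of all probe sets, near the levels of markers of other cell types, so the size of this fold is uncertain. EFEMP1, which encodes an extracellular matrix protein, rose 9.01-fold, and SREBF1, the transcription factor that drives fatty acid synthesis genes, rose 8.89-fold. In the other direction CXCL10, an interferon-inducible chemokine, was 5.94-fold lower, at 269 ± 23.9 against 1592 ± 71.5. LPCAT2, a lysophospholipid acyltransferase, was 3.63-fold lower, and the Tec family tyrosine kinases TXK and TEC were 3.34-fold and 3.09-fold lower. TXK was at a log2 level of 4.37 with ATRA, under single markers of other cell types such as CD8A (4.75), so its fold is uncertain. The log2 changes were 5.13 (SE 0.099, adjusted p = 1.69e-06) for CALCRL, 3.17 (SE 0.12, adjusted p = 4.31e-05) for EFEMP1, 3.15 (SE 0.085, adjusted p = 9.98e-06) for SREBF1 and -2.57 (SE 0.10, adjusted p = 5.07e-05) for CXCL10.

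The rest of the 10 largest increases were those of FBXO32 (3.03 on the log2 scale), HAPLN3 (2.76), MFGE8 (2.74), DDIT4 (2.71), GBP4 (2.49), CTSZ (2.40) and ULBP3 (2.27). FBXO32 encodes a substrate-binding subunit of a ubiquitin ligase, DDIT4 an inhibitor of mTORC1 signalling, CTSZ a lysosomal cathepsin and ULBP3 a surface ligand of an activating receptor of natural killer cells. HAPLN3 and MFGE8, neighbours in the genome, encode a hyaluronan-linking protein and a phosphatidylserine-binding secreted protein. Among the 10 largest decreases were also those of TMSB15A (-1.70), FAT1 (-1.62), CBLN2 (-1.54), CADM1 (-1.52) and PCP4 (-1.44). Each of these genes had an adjusted p under the threshold, the highest being 0.0306 for PCP4. The DMSO levels of GBP4 and ULBP3 and the ATRA levels of TMSB15A and CBLN2 lay among those of markers of other cell types, so the sizes and ranks of these changes are uncertain. With 1 array left out, GBP4 lost its call in 5 of the 6 fits (adjusted p up to 0.0789), PCP4 and CBLN2 in 4 each (up to 0.112 and 0.0654) and TMSB15A in 2 (up to 0.0575).

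**Figure D1:**
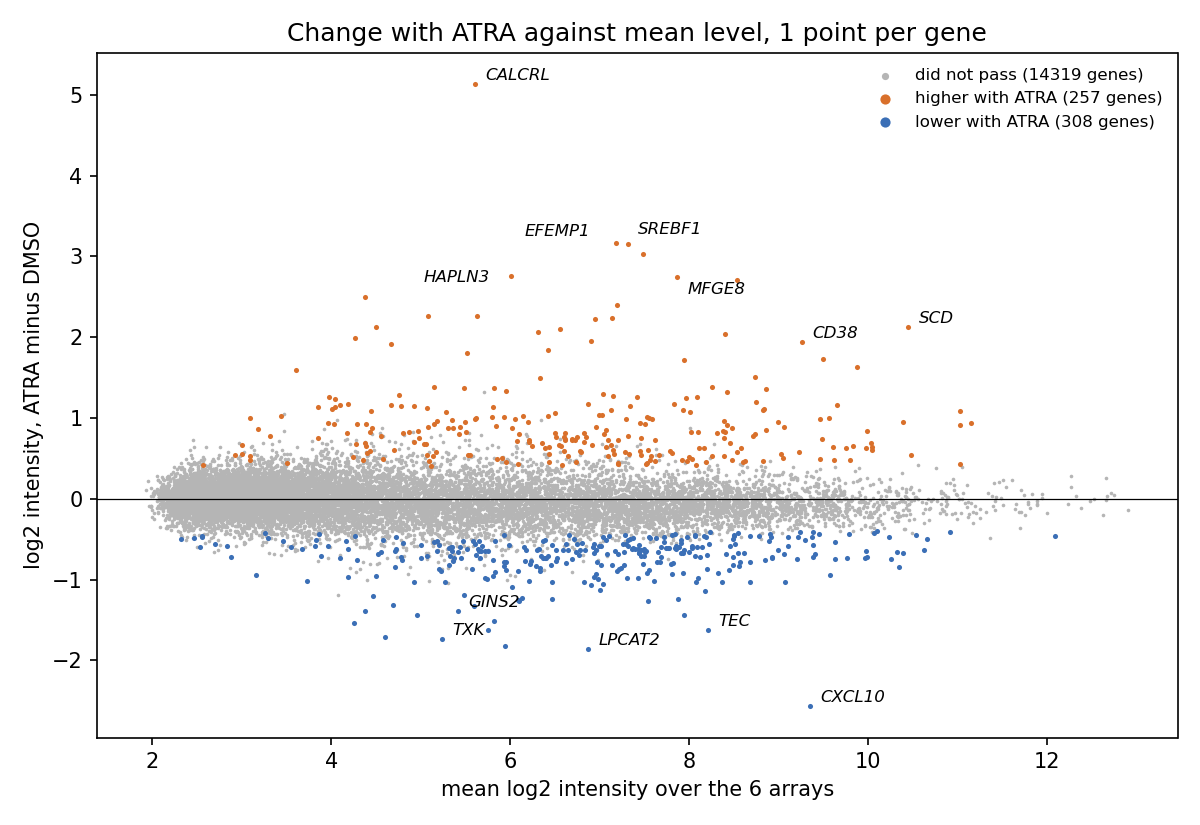
Log2 intensity change (ATRA minus DMSO, y axis) against mean log2 intensity over the 6 arrays (x axis), with 1 point per gene; orange points rose and blue points fell at an adjusted p under 0.05 (limma), and grey points did not pass. CALCRL at 5.13 and CXCL10 at -2.57 are the farthest points above and below 0.

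Of the 14884 genes tested, 565 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 257 of them higher and 308 lower with ATRA. A change of at least 2-fold was seen in 118 of these, 79 higher and 39 lower. Among the called genes, 232 protein-coding genes rose and 289 fell, beside 13 and 6 long non-coding RNA genes and 7 and 5 microRNA genes. The 3 ATRA values did not overlap the 3 DMSO values for any of the 565, and for 3671 genes in all (24.7%, where chance gives 10%). The median change of all genes was -0.01 on the log2 scale. The count fell whichever array was left out, to 207, 280 and 242 genes without DMSO replicate 1, 2 and 3 and 245, 317 and 251 without ATRA replicate 1, 2 and 3. A fit with fewer arrays has less power, so these falls do not point at any single array.

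A joint list of fatty acid synthesis genes and targets of the liver X receptors shifted up. These nuclear receptors pair with the retinoid X receptor. The test of the joint list does not tell synthesis genes from receptor targets. Of 14 measured members of this list of 18, 5 rose, 0 fell and 9 did not pass, and 7 rose adjusted over the list alone. In mean, 10 were higher and 4 lower. SREBF1 reached 476 ± 16.3 from 53.5 ± 1.28, and SCD, the desaturase that makes oleate, rose 4.36-fold to 2922 ± 89.6 from 670 ± 40.7 (SD, n = 3). ACACA, which makes malonyl-CoA, rose 2.14-fold, MYLIP, a ubiquitin ligase of the LDL receptor, 1.98-fold, and FASN, the fatty acid synthase, named after its value was seen, by 0.84 on the log2 scale. The median change of the list was 0.39, and limma's camera with a preset correlation of 0.01 gave an adjusted p of 9.14e-07 over the 26 lists tested (adjusted p = 0.0417 with an estimated correlation). In the list of cholesterol synthesis and uptake, 2 of 16 measured members rose, DHCR7 (0.63) and INSIG1 (0.63), while adjusted over the list alone 5 rose and 1 fell. The set did not pass (median 0.17, adjusted p = 0.0547). With 1 array left out, DHCR7 lost its call in all 6 fits (adjusted p up to 0.0758) and INSIG1 in 3 (up to 0.0579).

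DNA replication genes fell together. Of 26 measured members of a list of 40 genes of replication and S phase, 23 fell and 3 did not pass, and all 26 fell adjusted over the list alone. The decreases included GINS2 (-1.38), a subunit of the replicative helicase, CCNE1 (-1.07), the cyclin of S phase entry, MCM4 (-1.03), and CDT1 (-0.98), which loads the helicase at origins. The 6 helicase subunits MCM2 to MCM7, singled out after their values were seen, were all among them, from 1.60-fold to 2.04-fold lower. GINS2 was at a log2 level of 4.72 with ATRA, under single markers of other cell types such as CD8A (4.75), so its size is uncertain. Mitotic genes moved less, with 2 of 30 measured members past the threshold, MYBL2 (-0.95), a transcription factor of G2 and M phase genes, and CCNA2 (-0.47), the cyclin A gene. Adjusted over the list alone, 12 mitotic genes fell, and over all genes 14 did with eBayes with trend and robust, 10 and 5 without the dimmer 50% and 25% of genes and 5 among protein-coding genes alone. The list medians were -0.73 and -0.27, with camera adjusted p of 1.02e-27 and 2.88e-06 (adjusted p = 0.0417 with an estimated correlation for both lists). Leaving out 1 array brought the replication genes that fell to 14 without DMSO replicate 1, DMSO replicate 3 or ATRA replicate 3, and left 1 mitotic gene in each fit, since CCNA2 lost its call in all 6 (adjusted p 0.0783 to 0.113).

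Genes of ribosome biogenesis and MYC targets shifted down by camera (median -0.19, adjusted p = 0.000738), a call lost with an estimated correlation (adjusted p = 0.161). Among the 19 measured members 2 fell, LDHA (-0.55), lactate dehydrogenase A, and ODC1 (-0.46), the first enzyme of polyamine synthesis, and 5 fell adjusted over the list alone. MYC itself, an oncogene of myeloma, was at 2114 ± 34.5 with ATRA and 1880 ± 35.6 with DMSO, a log2 difference of 0.17 that did not pass (adjusted p = 0.350) but did with eBayes with trend and robust (adjusted p = 0.00501). With 1 array left out, ODC1 lost its call in all 6 fits (adjusted p up to 0.106) and LDHA in 5 (up to 0.130).

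Several genes known to respond to retinoic acid in other cell types rose. CD38, a surface ectoenzyme and target of myeloma antibodies, rose 3.85-fold, to 1207 ± 34.9 from 314 ± 24.8 (SD, n = 3), and PLAAT4, a phospholipase family gene first found as retinoid-induced, rose 3.58-fold. NRIP1, a nuclear receptor corepressor, rose by 0.81 on the log2 scale and ICAM1, an adhesion molecule, by 0.63. Of 17 measured members of this list of 31, 4 rose, 0 fell and 13 did not pass (5 rose adjusted over the list alone). The median of the members' mean log2 levels was 3.25, among the levels of markers of other cell types. Many members that did not pass may thus have been too dim to judge. The set shifted up by camera (median 0.12, adjusted p = 0.00767), a call lost with an estimated correlation (adjusted p = 0.130). Among retinoid receptor and metabolism genes, 6 of 24 were measured, of which RDH10, a retinol dehydrogenase, fell by 0.92 on the log2 scale, also adjusted over the list alone. DHRS3, a retinaldehyde reductase, was at a log2 intensity of 3.64 ± 0.32 with ATRA and 3.70 ± 0.085 with DMSO (SD, n = 3; difference -0.06, adjusted p = 0.886), which became 0.12 without ATRA replicate 3. Of the 6 measured members 4 lay among the levels of markers of other cell types, so the list's camera result (adjusted p = 0.709) says little about its genes. With 1 array left out, ICAM1 lost its call in all 6 fits (adjusted p up to 0.123) and NRIP1 in 4 (up to 0.0776), and NRIP1 also lost it with its 2 probe sets averaged (0.38 on the log2 scale, adjusted p = 0.171).

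IRF1, a transcription factor of the interferon response, rose 2.40-fold, to 420 ± 11.8 from 175 ± 5.33 (SD, n = 3), with an adjusted p of 0.000614. SOCS1, a feedback inhibitor of cytokine signalling, rose by 0.83 on the log2 scale from a level close to those of markers of other cell types, so its size is uncertain. These were the 2 of 12 measured interferon and interferon signalling genes that passed, 4 rose adjusted over the list alone, and the set shifted up (median 0.25, camera adjusted p = 0.000126; adjusted p = 0.0702 with an estimated correlation). Type I interferon-stimulated genes did not move as 1 block, since of 45 measured members 3 rose, 1 fell and 41 did not pass, with the same counts adjusted over the list alone. UBE2L6 (0.67), an enzyme of ISG15 conjugation, SP100 (0.59), a nuclear body protein, and SAMD9 (0.55), an antiviral factor, rose, and CXCL10 fell. Their camera call was close to the threshold (median 0.08, adjusted p = 0.0498) and was lost with an estimated correlation (adjusted p = 0.161). Members of the double-stranded RNA sensing list lay between -0.28 and 0.12. Of the 14 measured, 0 passed in limma's test, 0 had an unadjusted p under 0.05 and 0 passed in the ordinary two-sample test, with TLR3 at -0.28 and IRF7 at -0.12 as the largest differences (camera adjusted p = 0.709). With 1 array left out, SAMD9 lost its call in all 6 fits (adjusted p up to 0.144; 0.0573 with arrays shifted to a common median), UBE2L6 in 5 (up to 0.0614), SOCS1 in 4 (up to 0.0637) and SP100 in 3 (up to 0.0573), and the interferon-stimulated list lost its call without DMSO replicate 1 (0.152), DMSO replicate 2 (0.0644), ATRA replicate 2 (0.0791) and ATRA replicate 3 (0.104).

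**Figure D2:**
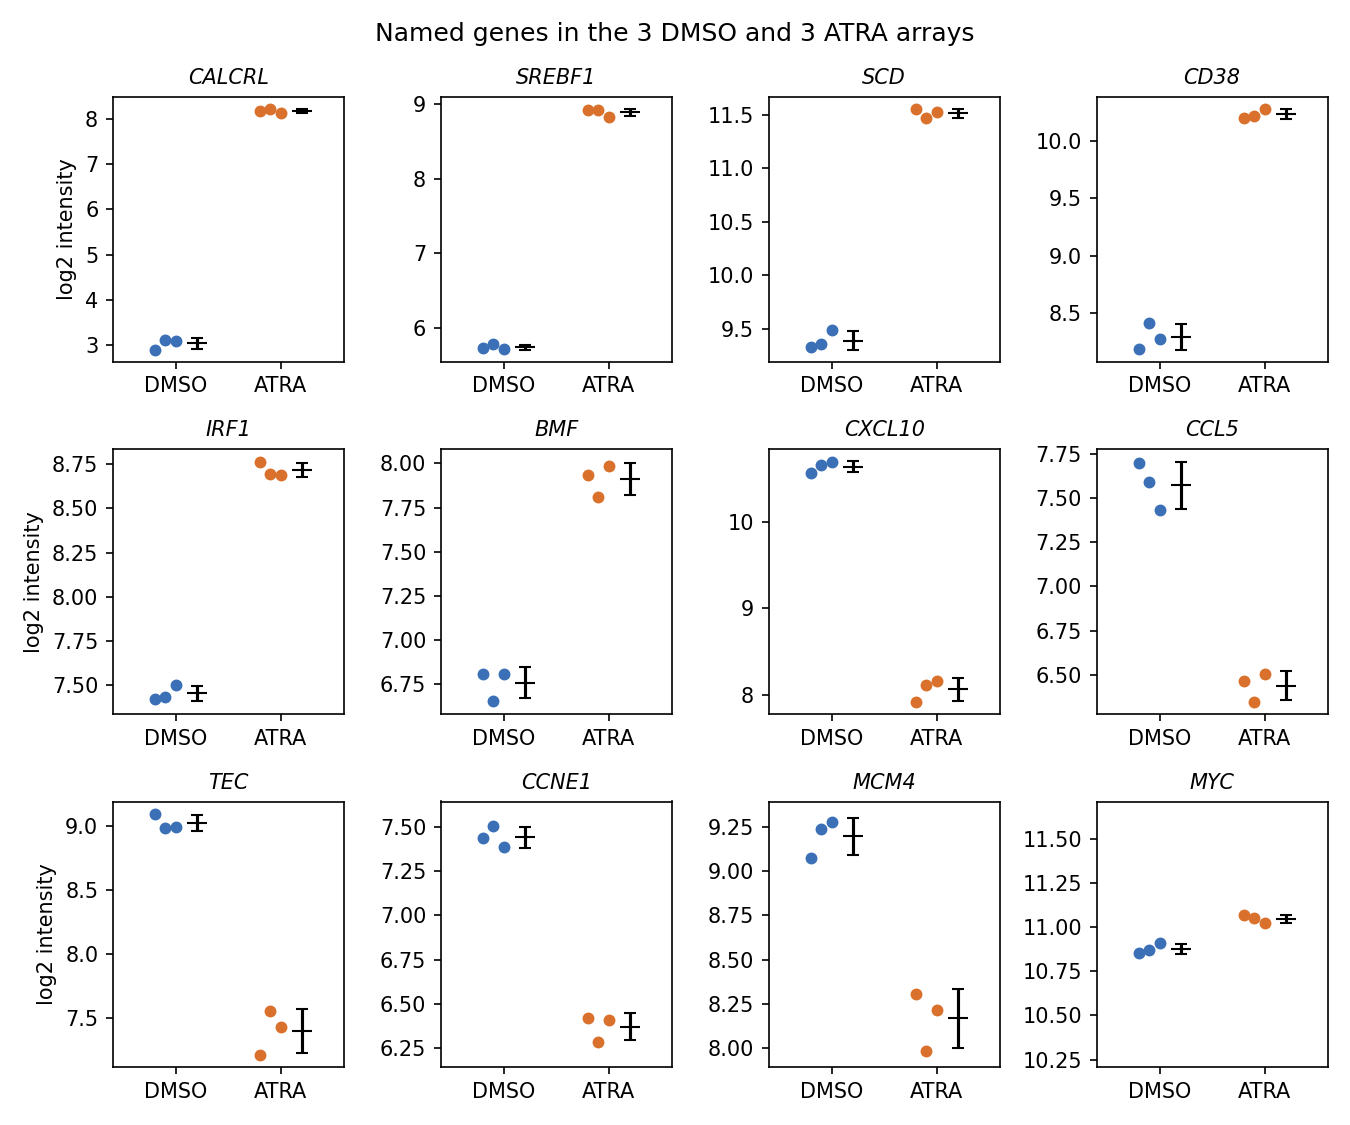
Log2 intensity (y axis) of 12 named genes on each of the 3 DMSO arrays (blue) and the 3 ATRA arrays (orange); the black bars give the mean and SD of each group. The groups do not overlap in any panel, and the difference for MYC, 0.17, did not pass the test.

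Genes that answer proteasome inhibition and protein misfolding moved in different directions. ERN1, the endoplasmic reticulum stress sensor IRE1, rose 2.00-fold, and XBP1, the transcription factor whose mRNA it splices, rose by 0.54 on the log2 scale. They were the 2 of 16 measured unfolded protein response genes that rose, also adjusted over the list alone, and the set did not pass (camera adjusted p = 0.269). In the ATF4 integrated stress response, 2 of 19 measured members rose, DDIT4 (2.71) and SESN2 (0.67), both inhibitors of mTORC1 signalling, while adjusted over the list alone 7 rose and 2 fell. This set shifted up (median 0.20, camera adjusted p = 0.00902; adjusted p = 0.130 with an estimated correlation). Among 17 measured cytosolic heat shock genes, the chaperone gene HSPA6 rose by 0.90 and HSPB1, a small heat shock protein, fell by 0.67. Adjusted over the list alone 6 rose and 1 fell, and the set shifted up (median 0.18, camera adjusted p = 0.0498; adjusted p = 0.169 with an estimated correlation). HMOX1, the heme oxygenase gene, fell by 0.64 and was the 1 of 12 measured NRF2 oxidative stress genes that passed, over all genes and adjusted over the list alone. The NRF2 set passed camera downward (median -0.12, adjusted p = 0.0362; adjusted p = 0.161 with an estimated correlation), but its median lay within the -0.19 to 0.07 of random lists matched on level, a comparison chosen after the result was seen. By the same comparison the unfolded protein response median (0.03) lay within its range of -0.17 to 0.05. The heat shock and ATF4 medians lay above theirs, -0.17 to 0.06 and -0.17 to 0.08. Left-out arrays ended the calls of XBP1 in all 6 fits (adjusted p up to 0.0758), SESN2 in 4 (up to 0.0632), HSPB1 without DMSO replicate 1 (0.0509), the NRF2 set in all 6 (0.0523 to 0.0791) and the heat shock set without DMSO replicate 1 (0.121), DMSO replicate 2 (0.0749) and ATRA replicates 1 (0.0605), 2 (0.0817) and 3 (0.0742). HSPA6 has a near-identical copy in the genome, so its value is uncertain.

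Of the constitutive proteasome, 3 of 39 listed genes were measured, and 0 passed in limma's test, had an unadjusted p under 0.05 or passed in the ordinary two-sample test. The largest differences were -0.14 for ADRM1 and -0.13 for SEM1, and 3 members are too few for a set test. ERAP1, the peptidase that trims peptides for MHC class I, rose by 0.59 and was the 1 of 5 measured immunoproteasome and antigen presentation genes that passed (2 rose adjusted over the list alone). The median of that list was -0.02, its mean 0.16 and its camera test upward without passing (adjusted p = 0.201). ERAP1 lost its call in 4 of the 6 fits with 1 array left out (adjusted p up to 0.0550). MHC class II genes and drug efflux transporters were not analysed here.

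Cell death genes changed on both sides. BMF, a BH3-only activator of apoptosis, rose 2.22-fold, to 241 ± 15.2 from 108 ± 6.43, and MCL1, an inhibitor of apoptosis on which myeloma cells often depend, rose 1.67-fold, to 930 ± 58.0 from 556 ± 13.9 (SD, n = 3). BMF was the 1 of 13 measured pro-apoptotic genes that passed, with 3 that rose and 1 that fell adjusted over the list alone. MCL1 was the 1 of 10 measured anti-apoptotic genes that passed, with 2 that rose and 1 that fell adjusted over the list alone. Neither set passed camera (adjusted p = 0.431 and 0.748), and the anti-apoptotic median was -0.09 where the mean was 0.01 and the test upward. Of 15 measured p53 targets, SESN2 rose, while 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.640).

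Plasma cell genes split as well. CD38 rose, SDC1, the plasma cell surface proteoglycan CD138, rose by 0.84 and XBP1 by 0.54, while CCND2, the cyclin D2 gene, fell by 0.74. The other 12 of 16 measured members did not pass, 4 rose and 3 fell adjusted over the list alone, and the set did not pass (median -0.01, mean 0.14, camera upward with an adjusted p of 0.384). IRF4 (-0.17, adjusted p = 0.383) and MAF (0.39, adjusted p = 0.0698), transcription factors of plasma cells and of some myelomas, did not pass. With trend and robust both did (adjusted p = 0.0307 and 0.000144), and MAF also did without the dimmer 50% or 25% of genes (0.0187 and 0.0458) and among protein-coding genes alone (0.0484). In the B cell list, STAP1 (0.82), a B cell adaptor protein, and CXCR5 (0.61), a homing receptor, rose among 15 measured members (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0899). The median of the members' mean log2 levels was 3.86, among the levels of markers of other cell types, so many may be too dim to judge. CXCR5 was at 4.39 with DMSO, under single markers such as CD8A (4.75 with ATRA), so its size is uncertain. STAP1 and CXCR5 lost their calls in 5 of the 6 fits with 1 array left out (adjusted p up to 0.121 and 0.0874).

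NF-kappaB target genes also went both ways, with 3 higher, 3 lower and 13 not past the threshold among 19 measured (3 higher and 5 lower adjusted over the list alone). IER3, a stress-induced survival gene, rose 2.52-fold, and the chemokine genes CCL3 and CCL5 fell by 1.26 and 1.13 on the log2 scale. ICAM1 rose by 0.63, and TNIP1 (0.53) and NFKB1 (-0.44), named after their values were seen, were the remaining pair. The set did not pass (camera adjusted p = 0.748). CCL3 has a near-identical copy, CCL3L1, named after its value was seen, whose difference of -0.17 did not pass, which makes the value of CCL3 uncertain. CCL3 lost its call in 4 of the 6 fits with 1 array left out (adjusted p up to 0.0609), and TNIP1 and NFKB1 in all 6 (up to 0.0905 and 0.134).

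**Figure D3:**
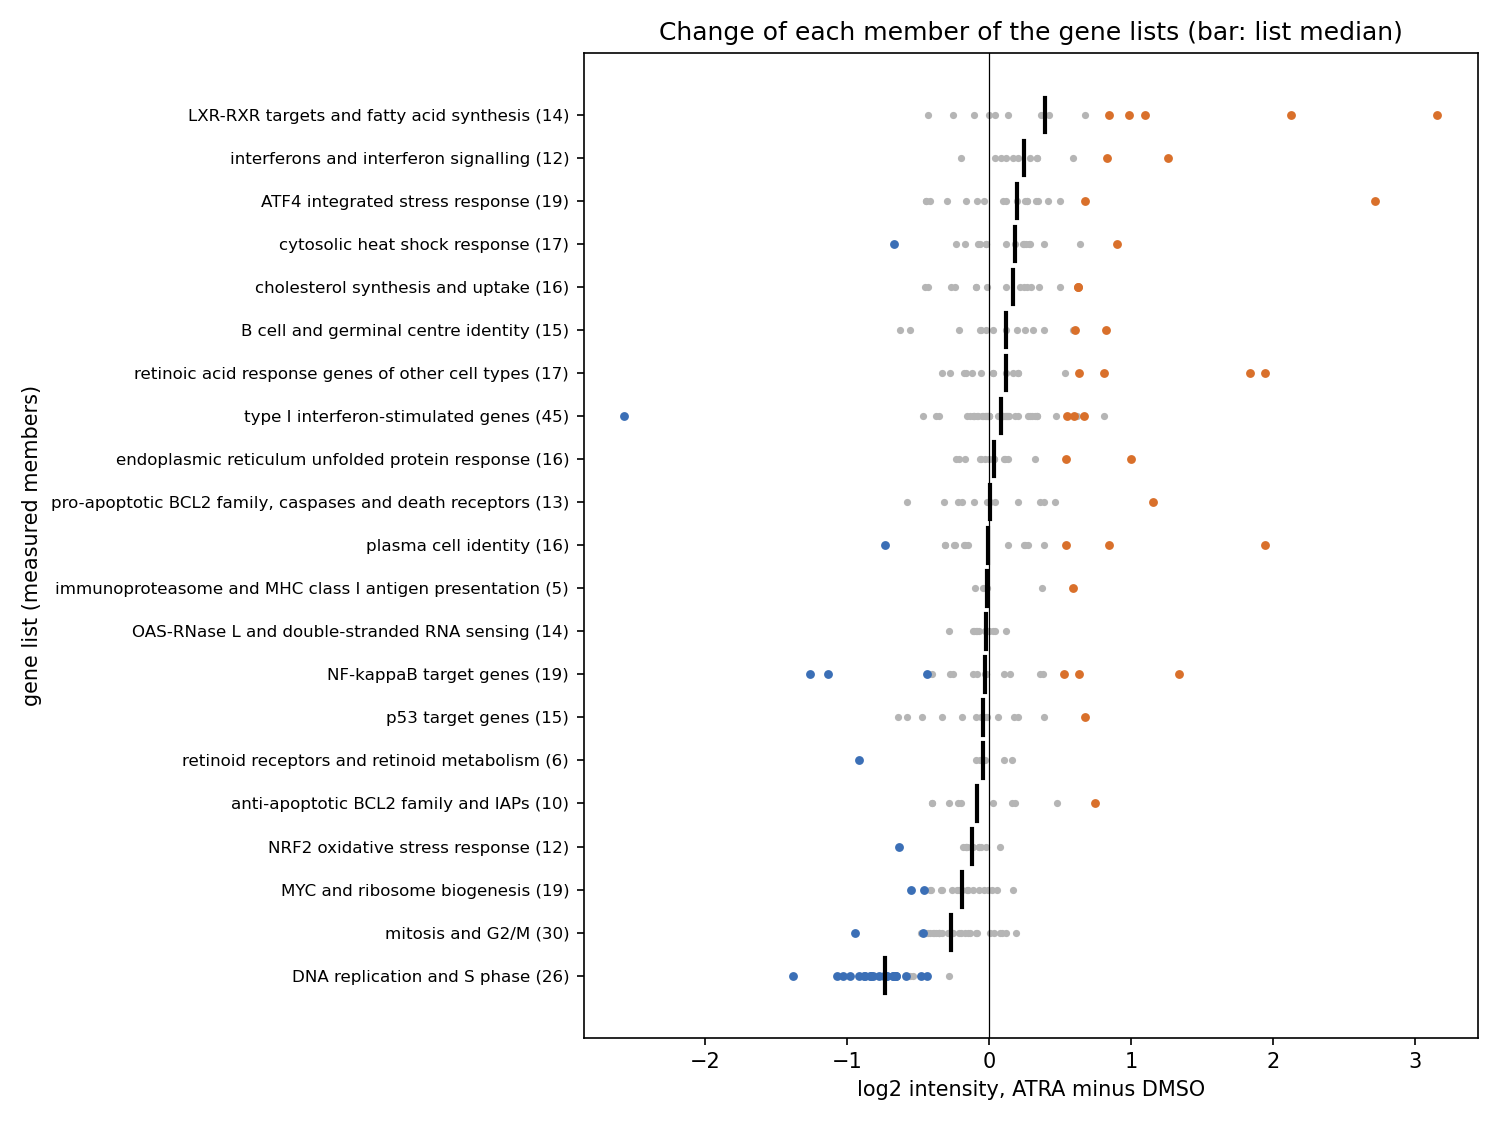
Log2 change (ATRA minus DMSO, x axis) of each measured member of the gene lists (y axis, number measured in parentheses); orange and blue points rose and fell at an adjusted p under 0.05, grey points did not pass, and black bars mark list medians. The replication list, with a median of -0.73, stands farthest to the left, and the fatty acid synthesis list, with a median of 0.39, farthest to the right.

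Markers of other cell types gave no call over all genes. Measured were 7 genes of T and NK cells, 10 of monocytes and macrophages, 6 of granulocytes, 5 of stromal cells, 6 of epithelial cells, 4 of endothelial cells and 1 of erythroid cells, and 0 passed in limma's test or in the ordinary two-sample test. At an unadjusted p under 0.05 stood 1 T and NK cell gene, 1 stromal gene and 1 erythroid gene, AHSP (0.23 on the log2 scale). AHSP was the 1 measured gene of its list, so adjustment over the list leaves its p unchanged and adds nothing. The lists' median log2 levels were low in both groups, between 2.47 and 3.99 with DMSO and between 2.70 and 3.94 with ATRA. Single markers lay higher, such as CD8A at 5.06 with DMSO and 4.75 with ATRA. Folds of genes whose lower level lay under these, TXK, PCP4 and HAPLN3 among them, are uncertain in size. Camera gave adjusted p of 0.449 to 0.867 for the 5 lists large enough to test, and the epithelial list had a median of -0.002 and an upward test. The largest differences were -0.31 for CD8A and -0.19 for CD2 among T and NK cells, 0.43 for S100A9 and 0.27 for CD14 among monocytes, and -0.22 for LTF and 0.10 for CSF3R among granulocytes. They were -0.42 for FN1 and -0.07 for LUM among stromal cells, -0.44 for EPCAM and 0.35 for KRT14 among epithelial cells, and 0.31 for CLDN5 and -0.25 for VWF among endothelial cells.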

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

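Tests of the replication genes and of CXCL10 described here were chosen only after the results were seen. The splits of the arrays were planned.

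Probe sets without a gene name here lie outside the comparisons of genes, and a signal appeared among them. Of 37519 such probe sets, adjusted over these alone with limma, 55 were higher and 21 lower with ATRA. The largest rise was 8.37 on the log2 scale for probe set 16707541, from 3.86 ± 0.091 with DMSO to 12.23 ± 0.028 with ATRA (SD of log2 values, n = 3). Its DMSO level lay in the range of markers of other cell types, so the size of the rise is uncertain. Probe set 17031373 was higher and 17017209 lower with ATRA, and as the lower level of each lay within or under that range, no size is given. Probe set 17104672 was 2.83-fold lower, but its log2 level with ATRA, 4.39, lay under single markers such as CD8A (4.75), so this size is uncertain. Their genes were not named here, and no explanation was tested for them.

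The 3 arrays of each group allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 565 genes where the highest of the others gave 0, 118 genes with at least 2-fold change where the highest of the others gave 0, and 10 called gene lists where the highest of the others gave 2. In each case 1 of the 10 splits, the real one, gave a result as large.

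The fall of replication genes was set against a technical trend. The arrays could differ in a way that moves all genes of a given level, but the list's median of -0.73 lay below all of 10000 random lists matched on mean level, whose central range was -0.16 to 0.03. The replication list also fell more than the mitosis list, by 0.51 on average (difference -0.51, between -0.54 and -0.46 over the 3 ATRA arrays). Each ATRA array was set against the DMSO mean, so this range leaves out the spread of the DMSO arrays. The lists did not fall equally, but a general slowing of the cell cycle need not lower both equally and is not excluded. A slower passage of ATRA-treated cells into S phase, or repression of these genes within cycling cells, may underlie the difference and was not tested. Arrays measure RNA per amount of RNA, so a change of total RNA per cell stays open.

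CXCL10 fell while the other interferon-stimulated genes did not fall as a set. Of the 45 measured, CXCL10 included, 25 were higher and 20 lower in mean. The median of the 44 others was 0.0838, with a bootstrap interval of -0.007 to 0.13 over genes, which are not independent replicates. A general fall close in size to that of CXCL10 was thus not seen. The list's median level with DMSO was 4.88 on the log2 scale, against 10.64 for CXCL10. A fall of dim members could therefore be missed and stays open. A general fall of chemokine genes cannot be told apart from a change of a few, because of the 5 other chemokine genes in the upper part of the intensity range 3 fell past the threshold (CCL3, CCL5 and CXCL16, the last at -1.22), while CCL3L1 (-0.17) and CXCL2 (-0.25) did not pass and 0 rose. CCL3 and CCL3L1 are near-identical copies, so their values are not separate evidence. When single arrays were left out, CXCL16 lost its call in 5 of the fits (limma, adjusted p up to 0.0921) and CCL3 in 4 (up to 0.0609). CCL5 kept its call in every such fit. The log2 change of CXCL16 stayed between -1.36 and -0.99. The count of 3 thus depends on which arrays are used. The falls of CCL3, CCL5 and CXCL16 had been seen before this test was set.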

How the results depend on the processing

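Many results depended on the alternatives, and the cause of each difference was not tested. Leaving out an array or adding a block lowers the power of the test, so a call lost there need not mean a changed effect. ODC1 and XBP1 lost their calls in all 6 fits with 1 array left out. Their log2 changes stayed between -0.47 and -0.45 and between 0.52 and 0.56. Of the 565 genes, 176 stayed called in all 6 fits with 1 array left out, and of the 10 called lists 3 kept their call with an estimated correlation. Among the lists that lost it, only the MYC list had an estimate (0.071) above the preset 0.01. The others had -0.041 (retinoic acid response), 0.00064 (interferon-stimulated), -0.031 (interferon signalling), -0.020 (heat shock), -0.029 (ATF4) and -0.078 (NRF2). A higher correlation between members therefore does not account for the losses of those other lists. For interferon signalling the unadjusted camera p rose from 1.93e-05 to 0.0108, although the estimate lay below the preset. The 2 settings thus differ in more than the correlation, and the losses of those other lists do not show a correlation above the preset. Protein-coding genes alone and leaving out genes with identical values were chosen after seeing the data. The 565 genes became 200 with the replicate block (113 higher, 87 lower), 207 to 317 with 1 array left out (112 to 152 higher, 95 to 165 lower), 1143 without the dimmer 50% of genes (436 and 707), 1327 with eBayes with trend and robust (494 and 833), 169 with treat (100 and 69) and 359 with every probe set by itself (149 lower). The ordinary two-sample test gave 170 higher genes. Genes with at least 2-fold change numbered 180 with every probe set by itself (132 higher) and 73 with the ordinary test (51 higher, 22 lower). Replication genes that fell numbered 12 with the replicate block and 14 to 16 with 1 array left out. Mitotic genes that fell numbered 1 with the replicate block and with any array left out, 10 and 5 without the dimmer 50% and 25% of genes, 14 with trend and robust and 5 among protein-coding genes alone. For lists, adjusted p are given. The interferon-stimulated genes had 0.0692 with the replicate block, 0.0334 to 0.152 with 1 array left out, 0.0552 without the dimmer 25%, 0.0953 with trend and robust, 0.161 with an estimated correlation, 0.0678 on ranks, 0.140 with fry, 0.0709 without genes of several lists and 0.0537 without identical values. The heat shock list had 0.0745 with the replicate block, 0.0334 to 0.121 with 1 array left out, 0.169 with an estimated correlation, 0.110 on ranks, 0.0622 without genes of several lists and 0.0984 without identical values. The NRF2 list had 0.0692 with the replicate block, 0.0523 to 0.0791 with 1 array left out, 0.0747 without the dimmer 50%, 0.120 and 0.142 with quantile and cyclic loess normalization and 0.161 with an estimated correlation. The retinoic acid response list had 0.130 with an estimated correlation, 0.127 on ranks and 0.130 without genes of several lists. The ATF4 list had 0.130 with an estimated correlation and 0.0967 on ranks, interferon signalling 0.0702 and the MYC list 0.161 with an estimated correlation. Calls gained were those of cholesterol synthesis (0.0209 and 0.0494 without the dimmer 50% and 25%, 0.0490 with 1 median, 0.0230 and 0.0182 with quantile and cyclic loess, 0.0247 with trend and robust, 0.0429 among protein-coding genes). The fry test asks whether a list changed at all and not whether it changed more than other genes, so its adjusted p are not calls of the same kind. They lay under the threshold for cholesterol synthesis (0.00141), B cell genes (0.0183), the unfolded protein response (0.00216), immunoproteasome (0.0226), plasma cell (0.00221) and pro-apoptotic genes (0.00921). The direction turned, without a call on either side, for NF-kappaB targets (0.571 and 0.959 without the dimmer 50% and 25%, 0.596 to 0.999 with 1 array left out, turned at 0.999 without ATRA replicate 3), anti-apoptotic genes (0.933 on ranks, 0.652 to 0.995 with 1 array left out, turned at 0.995 without ATRA replicate 2), epithelial markers (0.971 with fry, 0.652 to 0.985 with 1 array left out, turned at 0.985 without DMSO replicate 2 and 0.958 without ATRA replicate 2), granulocyte markers (0.596 to 0.911, turned at 0.906) and monocyte markers (0.345 to 0.973, turned at 0.973), both without ATRA replicate 3. DHRS3 lay between -0.16 and 0.12 on the log2 scale with 1 array left out and turned without ATRA replicate 3. With the replicate block 20 of the 59 called named genes were no longer called, among them HMOX1 (adjusted p = 0.0547), the 1 called NRF2 gene. Of all 59, 36 kept their calls in every alternative and 0 changed sign. The numbers 1 to 3 were not taken as pairing the arrays, although each of the 6 arrays deviated most like the array of the other group with its own number, with correlations of 0.0087 to 0.017.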

Other observations

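The tests of neighbouring genes and of FOXO and glucocorticoid targets were set, or their criteria changed, only after the results were seen, and the surface, sulfatase and Notch genes, PDCD4, HSD11B1, TOM1L2 and PLAAT2 were chosen after their values were seen. All of these were picked among called genes and were not tested as groups. CXCR4, the receptor that holds plasma cells in the bone marrow, rose by 1.73 on the log2 scale, to 1316 ± 73.1 from 398 ± 44.7 (SD, n = 3), and CCR10, another homing receptor, rose by 1.08. CXCR3, the receptor of CXCL10, fell by 0.99, and of cytokine receptor genes IL17RB rose by 1.13 while CRLF2 and IL6R fell by 1.03 and 0.50. Of genes encoding ligands of T and NK cell receptors, ULBP3 (2.27) and ICAM1 (0.63) were higher and CD70 (-0.80), CD58 (-0.76), CD48 (-0.67), ICOSLG (-0.57) and CD276 (-0.55) were lower. The log2 levels of CCR10 (4.74), IL17RB (4.51) and ULBP3 (3.95) with DMSO and of CD58 (4.41) with ATRA lay under single markers such as CD8A (4.75 with ATRA). The sizes of these changes are thus uncertain. With 1 array left out, CXCR4, CCR10, CRLF2 and ULBP3 kept their calls in all 6 fits, CXCR3 and CD70 lost theirs in 5 (adjusted p up to 0.0925 and 0.0962), CD58 and IL17RB in 3 (up to 0.0582 and 0.0589), and IL6R, ICAM1, CD48, ICOSLG and CD276 in all 6 (up to 0.129, 0.123, 0.0739, 0.0768 and 0.0947).

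Of the extracellular sulfatases that edit heparan sulfate, SULF2 rose by 1.63 (1660 ± 65.4 from 535 ± 24.2) and SULF1 fell by 1.02 (232 ± 8.81 from 473 ± 9.88; SD, n = 3). Of genes of Notch signalling the receptor gene NOTCH2 rose by 0.76 and NOTCH1 fell by 0.56, while the ligand gene JAG1 (0.95) and the target gene HEY2 (0.83) rose. SULF1, SULF2, JAG1 and HEY2 kept their calls with any 1 array left out, NOTCH2 lost its call without DMSO replicate 1 (adjusted p = 0.0509) and NOTCH1 in all 6 fits (up to 0.124).

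Neighbouring protein-coding genes were called in the same direction more often than shuffled calls gave, in 21 of 11887 pairs against a mean of 12.5 (one-sided permutation p = 0.0155, with 10000 shuffles among genes of like level). Neighbours here are protein-coding genes adjacent among those tested, at any distance, so genes that were not tested can lie between them. HAPLN3 with MFGE8, TXK with TEC, SREBF1 with TOM1L2 and PLAAT4 with PLAAT2 are such pairs. Their calls had been seen before the test was set and are counted in it, so its p-values are no independent evidence. Overlapping transcripts or shared probes may account for part of this, since without overlapping genes and identical probe values 18 pairs remained against a mean of 11.3 (one-sided permutation p = 0.0374). Without pairs whose symbols share their first 3 letters 16 remained against 11.0 (one-sided permutation p = 0.0904), but that filter is no full test of side-by-side paralogs, since it leaves in TXK with TEC, kinases of 1 family. Neither count lay above the upper end of the shuffled range, 18 in both tests, so these explanations cannot be told apart from a shared regulation of neighbouring genes.

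Because FBXO32, DDIT4, BMF and PDCD4 (1.51) rose, a candidate explanation is that FOXO target genes rose as a set. In a list written without these genes, 24 of 27 were measured, 2 rose and 1 fell, and camera gave an adjusted p of 0.634, so a general rise was not seen. HSD11B1, the enzyme that turns cortisone into cortisol, rose by 1.26 from a level among those of markers of other cell types, so its size is uncertain, and a rise of glucocorticoid target genes was tested in the same way. There 16 of 20 were measured, 1 rose and 2 fell, with a median of -0.08 and an adjusted p of 0.780. The bound first set for both lists, an adjusted p of 0.05 or more as evidence against a rise, was dropped, since a p that misses the threshold excludes no smaller shift, and both hypotheses remain open.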
